A study of Mus musculus with 1504 samples.

How the data were processed

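Single cells from the lungs of adult C57BL/6 mice were sorted by fluorescence into 384-well plates and sequenced with SMART-seq2, a method that copies and reads whole polyadenylated transcripts. The labels name 3 reporter groups: 769 cells of mice carrying eGFP under Cldn5 control (Cldn5-eGFP), 374 of Pdgfrb-eGFP mice and 361 of mice with Pdgfrb-eGFP and the NG2-dsRed reporter, where NG2 is the product of Cspg4. The sample labels give an age of 12 to 15 weeks and the series design 10 to 19 weeks. Neither names an animal, a plate or a date, so each population counted as 1 sample, no test across samples was possible and no p-value was computed.

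The authors deposited a table of raw read counts per gene and cell, and a table of scores made from them. Reads were aligned to mm10 with STAR 2.4.2a, per the submitters' processing notes. The counting program, the gene annotation and the authors' cell filter were not given in the sources used here. In the deposited score table, all 33008288 values were within 1 of the reads of a gene multiplied by 500000, divided by the cell's total and rounded, and the scores of a cell summed to between 498422 and 501788. The read counts were used for all results, and the scores only in alternatives. Column names give a set and a well: EC1, EC2, EC3, Mural1, Mural2 and Mural3. The EC sets were taken as Cldn5-eGFP because the design text says that this reporter labels endothelial cells. Mural1 and Mural2 together hold 361 columns and Mural3 holds 374, as many as the labels of the Pdgfrb reporter groups, but no column name gives a reporter, so comparisons planned between those reporter groups were made between the column sets under their own names. Mural1 and Mural2 were pooled for this after the files had been seen.

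Cells with at least 50000 reads were kept, which removed none. The table has 21947 genes, of which 21755 have a place in the GRCm38 annotation, the source of the coordinates given, which count from 1. Levels are CPM, a gene's share of the reads summed over the cells of a class. Intervals are exact at 95%: Poisson for summed reads, Clopper-Pearson for shares of cells above 0 and conditional for ratios of reads. SMART-seq2 reads carry no molecular identifiers and are not independent molecules, so intervals and floors cover counting error only. For a share of 0 the upper limit given is 3 cells of the total. Shares of cells with a read were taken after thinning each cell to 50000 reads, so that depth did not set them.

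A gene passed the size rule when its higher side had at least 50 CPM and at least 25% of that side's cells held a read after thinning, with a fold of at least 4, or of at least 2 between mural column sets, and at least 20 cells on each side. For the rule, the ranking by fold and the log2 differences, a side with fewer than 3 reads was set to 3 reads. Printed folds use this floor only for a side with no reads, which gives a lower bound. Where a side held some reads but fewer than 3, the printed fold uses the reads as counted and is larger than the one ranked. The genes named are the 10 with the largest fold in each direction, up to 4 members of each fixed gene list (those past the rule by fold, then by CPM) and the reporter genes. Predicted or unnamed genes, ribosomal protein genes and mitochondrial genes were counted and not named. The size rule, the rule for names, 17 gene lists (434 entries, 424 distinct genes, 432 entries measured), 20 lists of cell type markers (156 of 160 markers measured) and most alternatives were fixed before the data were examined.

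Cells were clustered from log values per 10000 reads of 2000 variable genes, with 30 principal components, 15 neighbours and the Leiden method at resolution 1 and seed 1. So that class comparisons rested on genes the clusters had not used, 11103 genes were held out: the functional lists, the reporters and a random part of the other genes that were no markers. The 10844 others could be used. Clusters were named "X-like" from the fixed markers. A cluster whose cells held, averaged over the markers of the epithelial or the leukocyte list, at least 50% of them stayed unnamed and was called mixed. A class name needed at least 40% for its own markers. Both thresholds were set after the files had been seen, and the share of each unnamed cluster is given per population. Class comparisons ran over the held-out genes and comparisons of whole populations or of 1 cluster between populations over all genes. No doublet caller was run. Cells with reads of at least 5 endothelial markers and at least 5 markers of the pericyte, smooth muscle or fibroblast lists after thinning were counted as doublet-like, kept, and left out in an alternative. For the lists over classes, a gene needed at least 10 CPM in some class, chondrocyte- or perichondrial-like cells included. To be placed it needed a 2-fold lead among the pooled endothelial, mural (pericyte- and smooth muscle-like) and fibroblast classes only.

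The size rule was tested on simulated data with known folds, drawn from the reads of these cells with 200 of 21947 genes altered, 50 at each of 2-, 4-, 8- and 16-fold. In Cldn5-eGFP against Mural3, 50%, 100% and 94% of genes with a true 4-, 8- and 16-fold difference passed, and 0 of 21747 unaltered genes. Genes under 50 CPM on both sides cannot pass at any fold. For the 22 lymphatic-like cells, 88% of genes with a true 8-fold difference passed. Of unaltered genes 171 of 21747 passed there, 84 of them among the 10983 that this comparison ran over. For cluster 10 in Mural3, with 23 cells, 33 unaltered genes passed, 12 of them among the 10990 compared. For cluster 2 between the mural populations 148 unaltered genes of all 21747 passed at 2-fold. In pericyte- against smooth muscle-like cells 4 did and in aerocyte-like against other endothelial cells 4, of which 3 and 1 were among the genes compared. Clustering of 1504 simulated cells from 13 known clusters returned 13 clusters with an adjusted Rand index of 1. The simulated cells were drawn from the profiles of the clusters found here, so this index does not show that the real clusters are stable.

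Alternatives were means over cells of the CPM per cell, the authors' scores, edgeR TMM and DESeq2 median-ratio scaling factors, at least 200000 reads per cell, no minimum CPM or share, 8-fold (4-fold between mural sets), thinned cells, resolutions of 0.5 and 2, all genes or the other random part of the genes, 1000 variable genes, assignment by marker score, and doublet-like cells left out. Leaving out clusters 4 and 8, leaving out each column set, TMM factors for class comparisons and fibroblast-like cells of Mural1 and Mural2 alone were added after seeing the data. Reads of closely related genes (the H2, Ly6, actin and C1s families) and of overlapping or antisense genes can be shared between them, and their values are uncertain, since the counting program and its use of strand were not given in the sources used here. Some list genes that were analysed are not reported here. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.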

Results

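Expression was measured in 1504 single cells of mouse lung sorted for vascular reporters. The cells lay in 6 column sets. EC1, EC2 and EC3, with 243, 275 and 251 cells, came from the endothelial reporter Cldn5-eGFP. Mural1 and Mural2, with 128 and 233 cells, and Mural3, with 374 cells, held cells sorted for reporters of mural cells, which wrap blood vessels as pericytes or smooth muscle and share Pdgfrb with fibroblasts. Reads in genes ran from 100229 to 609242 per cell, with a median of 240178. The median was 198570 reads and 1909 genes in Cldn5-eGFP cells, 251676 reads and 4153 genes in Mural1 and Mural2, and 367962 reads and 3996 genes in Mural3. Each population was 1 sample, so no difference below has a replicate check, and every interval covers counting error only. Bounds after a fold are its 95% counting interval, and "passed" means past the size rule. A side with no read was set at 3 reads to give an "at least" fold. A side with some reads but fewer than 3 was not raised in the folds printed.

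The reporter genes separated the populations. Cldn5, a tight junction gene of endothelium (chromosome 16, 18776847 to 18778262 in GRCm38), stood at 11023 CPM (11007 to 11039) in Cldn5-eGFP cells, 53.8 CPM (52.3 to 55.3) in Mural1 and Mural2 and 9.42 CPM (8.91 to 9.95) in Mural3. Pdgfrb, the receptor that recruits mural cells (chromosome 18, 61045127 to 61085067), stood at 1.43 CPM (1.25 to 1.62), 1281 CPM (1273 to 1288) and 374 CPM (371 to 377) in the same order. Its level in Cldn5-eGFP cells was 0.402 CPM (0.291 to 0.541) without EC3, so its fold against Mural1 and Mural2, given below, is larger without that set. Cspg4, which encodes NG2 (chromosome 9, 56865104 to 56899870), stood at 78.3 CPM (77.0 to 79.7), 457 CPM (453.0 to 462) and 42.6 CPM (41.5 to 43.7). After thinning, Cldn5 reads were found in 99.6% of Cldn5-eGFP cells, against 21.9% of Mural1 and Mural2 cells (7.03% in Mural1 and 30.0% in Mural2) and 6.68% of Mural3 cells. Pdgfrb reads were found in 1.30%, 97.2% and 97.6%, and Cspg4 reads in 28.9%, 83.4% and 40.4%.

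Clustering gave 13 clusters, and the sorts set what each population could hold. Of the 769 Cldn5-eGFP cells, 85.6% (82.9 to 88.0) were general capillary-like, 9.62% (7.63 to 11.9) aerocyte-like, the type of thin capillary cell rich in Car4, and 2.86% (1.80 to 4.30) lymphatic-like. No arterial or venous cluster formed. None of the 769 was pericyte-, smooth muscle- or fibroblast-like, which allows a share of up to 0.390%. Mural1 and Mural2 held 18.8% (14.9 to 23.3) pericyte-like, 19.4% (15.4 to 23.9) smooth muscle-like, 23.5% (19.3 to 28.3) fibroblast-like and 12.2% (9.00 to 16.0) chondrocyte- or perichondrial-like cells, and 2 general capillary-like cells. Mural3 held 83.7% (79.6 to 87.3) fibroblast-like cells, 1 smooth muscle-like cell and no pericyte-like cell, which allows up to 0.802%. The fibroblast-like cells fell into cluster 2 (17.7% of Mural1 and Mural2, 20.6% of Mural3), cluster 3 (1.39% and 34.0%), cluster 5 (1.94% and 23.0%) and cluster 10 (2.49% and 6.15%). Clusters 3 (127 of 132 cells) and 5 (86 of 93) lay mostly in Mural3, clusters 11 (21 of 23) and 13 (18 of 21) in Mural1, and, less so, cluster 10 (23 of 32) in Mural3 and clusters 4 (69 of 97) and 7, the smooth muscle-like one (54 of 71), in Mural2. Each may in part be that set, not a type. Smooth muscle-like cells made up 12.5% (7.32 to 19.5) of Mural1 and 23.2% (17.9 to 29.1) of Mural2, chondrocyte- or perichondrial-like cells 30.5% and 2.15%, cluster 5 3.12% and 1.29%, cluster 10 1.56% and 3.0%, and aerocyte-like cells 7.00% (4.13 to 11.0), 8.36% (5.38 to 12.3) and 13.5% (9.57 to 18.4) of EC1, EC2 and EC3.

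Clusters 4 and 8 stayed unnamed. In cluster 4, 84.7% of marker and cell pairs of the epithelial list and 66.7% of the leukocyte list had a read after thinning, and in cluster 8 71.8% and 43.3%, against 9.33% and 2.21% in the general capillary-like cluster. They held 25.5% (21.1 to 30.3) of Mural1 and Mural2 cells, 16.0% (12.5 to 20.2) of Mural3 and 1.95% (1.10 to 3.20) of Cldn5-eGFP cells. Cluster 4 alone took 20.5% of Mural1 and Mural2 and 4.55% of Mural3, and cluster 8 took 4.99% (0 of 128 cells of Mural1 and 18 of 233 of Mural2) and 11.5%. The share of both was 3.91% in Mural1 and 37.3% in Mural2. In Mural2, 84.1% (73.3 to 91.8) of cluster 4 cells lay in plate rows G to L, which held 39.9% of all its cells, and in Mural3 66.7% (53.3 to 78.3) of the cells of both clusters lay in rows A to D, which held 24.6%. Doublet-like cells made up 44.3% of cluster 4, 15.7% of cluster 8 and 1.57% of the other 1337 cells. These clusters entered no class comparison but stayed in the comparisons of whole populations.

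**Figure D1:**
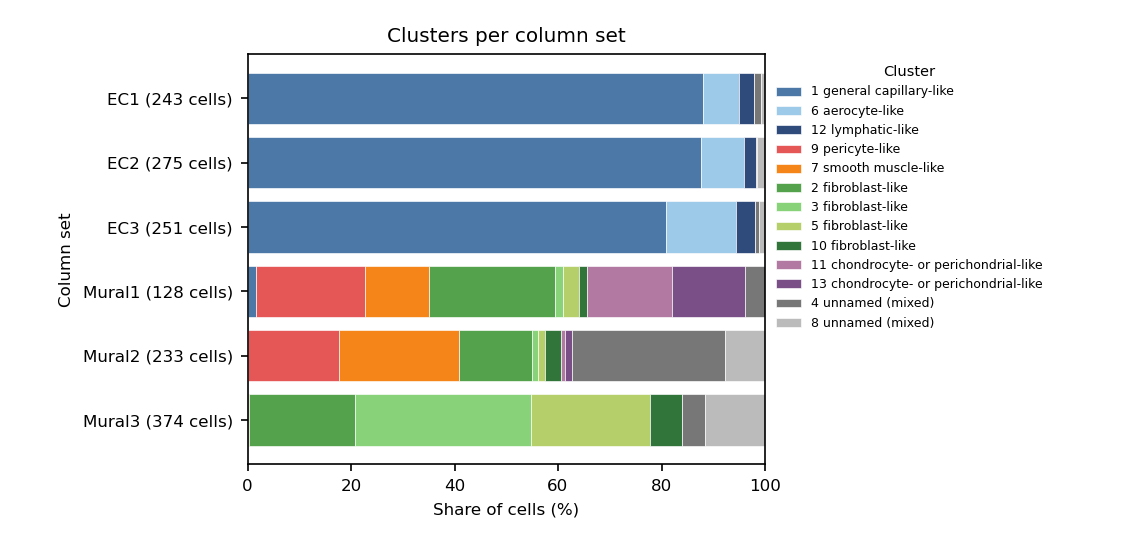
Bars give the share of cells (percent, x axis) of each column set (y axis) in each of the 13 clusters. General capillary-like cells fill most of EC1, EC2 and EC3, pericyte- and smooth muscle-like cells appear in Mural1 and Mural2, and fibroblast-like clusters make up 83.7% of Mural3.

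**Figure D2:**
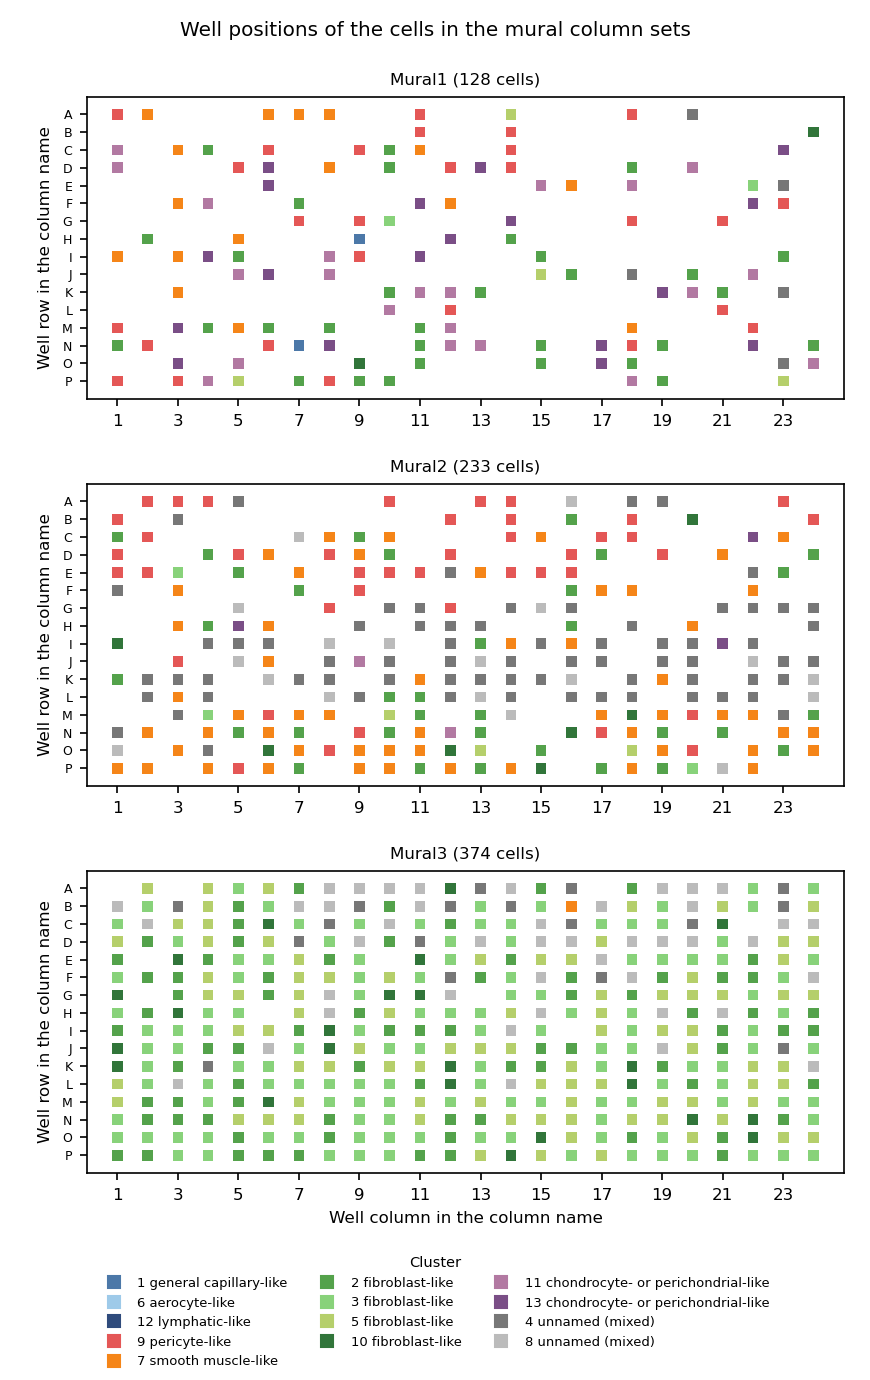
Each square is a cell at the well row (y axis) and well column (x axis) given in its name, coloured by cluster, for Mural1 (128 cells), Mural2 (233) and Mural3 (374). Cluster 4 cells of Mural2 lie mainly in rows G to L (84.1%), and cells of clusters 4 and 8 of Mural3 mainly in rows A to D (66.7%).

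Cldn5-eGFP cells were set against Mural3 cells to ask which genes separate lung endothelium from cells of this sort, which were mostly fibroblast-like. Of 21947 genes 1014 passed, 448 higher in Cldn5-eGFP cells and 566 lower. Among the largest folds on the first side were Cldn5 (1170-fold, 1108 to 1238) and the guidance receptor Robo4 (701-fold, 552 to 905). The endothelial surface genes Cd93 (478-fold, 448 to 511), Ptprb (365-fold, 346 to 385) and Cdh5 (342-fold, 319.8 to 366), the last encoding VE-cadherin, were also on this side. So were the transcription factor Sox18 (436-fold, 386 to 496) and the sphingosine phosphate exporter Spns2 (368-fold, 311 to 439). Ccm2l (472-fold, 373 to 607), Clec1a (392-fold, 357 to 433) and Podxl (360.5-fold, 334 to 389.5) joined them. On the Mural3 side the complement protease C1s1 (15332-fold, 9576 to 26320) and the matrix proteoglycan Dcn (3767-fold, 3554 to 3996) were among the 10 largest folds. The prostaglandin receptor Ptgfr (39332-fold, 7059 to 1553570, 1 read on the lower side) and the endothelin receptor Ednra (12665-fold, 3506 to 104588, 2 reads on the lower side) were too. The chemokine Ccl11 (3455-fold, 2447 to 5051), Dkk3 (5157-fold, 2716 to 11278) and Rarres2 (4756-fold, 3045 to 7900) followed. Tmem119 (3834-fold, 1761 to 10448), C7 (3637-fold, 2819 to 4777) and Spon2 (3474-fold, 2198 to 5862) were the remaining ones. Of the marker lists, 11 of 12 endothelial and 7 of 7 general capillary markers were higher in Cldn5-eGFP cells, and 10 of 10 fibroblast and 8 of 8 adventitial fibroblast markers were lower. None of 11 pericyte and none of 11 smooth muscle markers passed.

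Of 41 vasoactive receptors measured, 5 were higher in Cldn5-eGFP cells, among them the adrenergic receptor Adrb1 (260.4-fold, 220.2 to 310.2) and the calcitonin-receptor-like gene Calcrl (180.2-fold, 173 to 188), 4 were lower and 32 did not pass. Of 20 potassium channel genes, 3 were lower, Kcne4 (386-fold, 328 to 458) and the KATP channel genes Abcc9 (95.7-fold, 88.3 to 104) and Kcnj8 (17.5-fold, 16.8 to 18.2). Among 26 calcium channel and store genes, 1 passed, the mechanosensitive channel Piezo2 (26.2-fold, 24.8 to 27.6). The list of PDGF, VEGF, angiopoietin and Notch signalling had 8 higher and 5 lower of 27, with Notch4 (178-fold, 157 to 203) and the VEGF receptor Kdr (146-fold, 137 to 156) on the endothelial side and the Notch target Heyl (126-fold, 109.7 to 146) on the other. TGF-beta and BMP signalling had 7 higher, including Bmp6 (303-fold, 263 to 350.1) and Smad6 (25.9-fold, 24.4 to 27.6), and 4 lower of 28, including Bmp5 (37.9-fold, 34.7 to 41.4) and Fst (54.5-fold, 47 to 63.5). Of 21 pulmonary hypertension risk genes, 7 were higher, including Bmpr2 (22-fold, 21.6 to 22.4) and Sox17 (264-fold, 224 to 314), and 1 was lower, Tbx4 (68.7-fold, 58.1 to 81.8).

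Of 27 genes of fibrillar and elastic matrix 17 were lower in Cldn5-eGFP cells and none higher, with Col3a1 (2003-fold, 1884 to 2132), Col6a1 (1202-fold, 1073 to 1350) and Col6a2 (1889-fold, 1595 to 2255). Basement membrane genes were lower in 9 of 21 cases, including Lama2 (228-fold, 209.9 to 249), Col4a5 (281-fold, 231 to 346) and Hspg2 (38.6-fold, 36.9 to 40.3), and higher in 1. Complement genes were lower in 10 of 14, with C4b (1438-fold, 1250 to 1663) and the inhibitor Serping1 (883-fold, 839 to 929). Niche growth factor and WNT genes were lower in 8 of 30, including Igf1 (136-fold, 125 to 148), Il33 (114-fold, 104 to 125) and Sfrp1 (83.2-fold, 76.1 to 91.2). The dissociation stress list had 10 of 16 lower and none higher, with Fos (117-fold, 114 to 121), Egr1 (92.2-fold, 89.9 to 94.5), Nr4a1 (157-fold, 149.5 to 166) and Fosb (260.4-fold, 225 to 303). Of 24 chemokines and cytokines 2 were lower, Ccl8 (at least 2947-fold) and Cxcl14 (69.4-fold, 62.7 to 77), and the most abundant member, Cxcl12 (713 against 1347 CPM), did not pass.

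Of the remaining lists, 5 of 15 antigen presentation genes were higher in Cldn5-eGFP cells and none lower, including Tap1 (9.48-fold, 9.14 to 9.82), H2-Ab1 (5.82-fold, 5.74 to 5.89) and H2-D1 (5.57-fold, 5.53 to 5.62). Haemostasis, nitric oxide and prostanoid genes gave 5 higher and 4 lower of 28. Icam2 (276-fold, 257 to 296) and the vasoconstrictor gene Edn1 (79.9-fold, 74.1 to 86.3) were on the endothelial side, and tissue factor, F3 (146-fold, 130.1 to 164), and Serpine2 (45-fold, 42 to 48.1) on the other. Lipid handling gave 3 higher, led by the fatty acid carrier Cd36 (71.5-fold, 70.2 to 72.8), and 4 lower of 25, with Abca8a (2352-fold, 1815 to 3105) and Apoe (257-fold, 247 to 268). The list of genes known from brain endothelium, mostly transporters, gave 3 higher, including Abcb1a (8.79-fold, 8.34 to 9.27) and Slc3a2 (7.25-fold, 7.15 to 7.36), 1 lower, Slco2b1 (15-fold, 14.4 to 15.5), and 27 that did not pass. Developmental transcription factors gave 4 higher and 5 lower of 38, the latter including Prrx1 (1023-fold, 728 to 1486) and Meox2 (752-fold, 519.8 to 1131). All 1014 genes had the same direction in EC1, EC2 and EC3, and 908 had the fold in each, with a wide range for Dcn (1924- to 22327-fold). Such counts are no independent check, since here and below the genes were chosen on the pooled sets, and here the 3 were set against the same Mural3 cells. Leaving out EC1, EC2 or EC3 moved the fold of 9, 15 and 10 of 76 named genes that passed by over 1.5 times, among them Sfrp1 (log2 difference of -6.38, and -10.37 without EC2). TMM factors shifted the median log2 difference by -0.42 and gave 367 higher and 700 lower, and median-ratio factors, with a shift of -0.44, gave 363 and 710. No named gene that passed turned direction under the scalings tried in any comparison.

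Against Mural1 and Mural2, which held pericyte- and smooth muscle-like cells, 930 genes passed, 349 higher in Cldn5-eGFP cells and 581 lower. The endothelial side was led by Cldn5 (205-fold, 199 to 211) and Cyyr1 (99.7 against 1.07 CPM, 93.4-fold, 77 to 114). The lipase anchor of capillaries Gpihbp1 (1259 against 17.5 CPM, 72-fold, 68.6 to 75.6), Cd93 (74.2-fold, 72 to 76.5) and Cdh5 (71.9-fold, 69.4 to 74.6) were among its largest folds. It also held the transcription factor Sox17 (272 against 4.24 CPM, 64.2-fold, 58.2 to 70.9). Of the 5191 Cldn5 reads in Mural1 and Mural2, 2643 lay in the 92 cells of clusters 4 and 8. Cldn5 stood at 126 CPM there and at 25.5 CPM in chondrocyte- or perichondrial-like cells. It stood at 25.1 CPM in smooth muscle-like, 17.6 CPM in fibroblast-like and 1.27 CPM in pericyte-like cells. The fold of Cldn5 thus depends on which wells are included. The largest folds on the mural side belonged to the endothelin receptor Ednra (0.0122 against 258 CPM, 21117-fold, 5845 to 174381, 2 reads on the lower side) and to Dkk3 (0.0551 against 606 CPM, 11006-fold, 5798 to 24071) and C1s1 (5723-fold, 3574 to 9824). Postn (0.881 against 1722 CPM, 1954-fold, 1660 to 2317), which encodes periostin, and the transcription factor Foxf2 (0.049 against 93.4 CPM, 1907-fold, 967 to 4419) followed. Dcn (1628-fold, 1535 to 1727), Tmem119 (3094-fold, 1421 to 8432) and C7 (2069-fold, 1603 to 2718) were also among the 10 largest. The reporter genes Pdgfrb (898-fold, 789.8 to 1026) and Cspg4 (5.84-fold, 5.72 to 5.96) were higher in the mural sets. Pericyte markers were higher there in 9 of 11 cases and smooth muscle markers in 10 of 11, as were 10 of 10 fibroblast markers. Beside them, 6 of 11 epithelial markers and 1 of 9 leukocyte markers, Lyz2, were higher in the mural sets. Sftpc and Lyz2 were far higher in cluster 4, as given below.

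Of 41 vasoactive receptors 6 were higher in the mural sets, including Ednra, the sphingosine phosphate receptor S1pr3 (81.8-fold, 75.6 to 88.7) and P2ry14 (38-fold, 34.8 to 41.7), and 5 were higher in Cldn5-eGFP cells, including Calcrl (37-fold, 36.2 to 37.8). Potassium channel genes were higher in the mural sets in 4 of 20 cases, with Kcnk3 (117-fold, 104 to 131), whose loss-of-function variants cause pulmonary hypertension, Kcne4 (158-fold, 135 to 188) and Abcc9 (57.8-fold, 53.2 to 62.8). Calcium genes were higher in 4 of 26, including the L-type channel Cacna1c (7.22-fold, 6.93 to 7.52) and the chloride channel Ano1 (14.3-fold, 13.2 to 15.5), and lower in 1. PDGF, VEGF, angiopoietin and Notch genes split into 8 higher in Cldn5-eGFP cells, with Pdgfb (28.8-fold, 27.5 to 30.2), Kdr (41-fold, 39.4 to 42.7) and Notch4 (36-fold, 33.7 to 38.5), and 6 higher in the mural sets, with Heyl (265-fold, 230.2 to 306). For TGF-beta and BMP genes the split was 6, with Bmp6 (41.6-fold, 39.1 to 44.3), to 5, with Ltbp2 (188-fold, 169 to 208). Pulmonary hypertension risk genes split 7 to 2, the mural members being Kcnk3 and Tbx4 (135-fold, 114 to 161).

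Higher in the mural sets were 19 of 27 fibrillar and elastic genes, with Col3a1 (898-fold, 845 to 956) and Col6a2 (1143-fold, 965 to 1365), and 9 of 21 basement membrane genes, with Vtn (43-fold, 38.8 to 47.8) and Lama2 (114-fold, 105 to 125). Complement gave 9 of 14, with Serping1 (338-fold, 322 to 356) and C4b (319-fold, 278 to 369). Stress genes gave 10 of 16, with Fos (99.9-fold, 97 to 103) and Hspa1a (143-fold, 128 to 159.5). Niche factors gave 5 of 30, with Igf1 (98.4-fold, 90.7 to 107), Il33 (50.6-fold, 46.1 to 55.6) and Wnt5a (39.5-fold, 34.8 to 44.9). Haemostasis genes split 5 to 5 of 28, with Edn1 (43.4-fold, 40.6 to 46.5) against F3 (372-fold, 332 to 418) and Serpine2 (115-fold, 107 to 123). Lipid genes split 3 to 6 of 25, the mural side holding Abca8a (1197-fold, 924 to 1581), Lrp1 (78.1-fold, 74.7 to 81.8) and Apoe (72.7-fold, 69.8 to 75.7). Of the 31 genes of the brain endothelial list 2 were higher in Cldn5-eGFP cells, Abcb1a (20.9-fold, 19.1 to 23) and Slc3a2 (6.13-fold, 6.03 to 6.22), and 2 lower, Foxf2 and Tfrc (12.9-fold, 11.9 to 13.9). Antigen presentation genes were higher in Cldn5-eGFP cells in 4 of 15 cases, with H2-K1 (6.6-fold, 6.54 to 6.66) and H2-D1 (6.5-fold, 6.44 to 6.57). Chemokines gave 1 of 24, Cxcl14 (30.5-fold, 27.6 to 34), while Cxcl12 (713 against 659 CPM) did not pass. Transcription factors split 4 to 5 of 38, the mural side including Prrx1 (922-fold, 656 to 1340) and Tbx5 (64.6-fold, 56.7 to 73.8). All 930 genes had 1 direction in the 3 EC sets and 828 the fold in each. Leaving out EC1, EC2 or EC3 moved 10, 14 and 8 of 77 named genes by over 1.5 times, Mural1 6 and Mural2 24, among them Cyyr1 (6.55, and 10.25 without Mural2).

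Mural1 and Mural2 against Mural3, at the 2-fold rule, gave 669 genes, 455 higher in Mural1 and Mural2 and 214 higher in Mural3. Among the largest folds on the first side were the actin gene Actc1 (2582 against 2.44 CPM, 1058-fold, 949 to 1183), smooth muscle myosin Myh11 (1577 against 4.23 CPM, 373-fold, 343 to 405) and calponin Cnn1 (209-fold, 187 to 234). The channel Trpc6 (294-fold, 229 to 382) and the pericyte genes Higd1b (108 against 0.373 CPM, 289-fold, 219 to 389.9) and Cox4i2 (137-fold, 119.7 to 158) were also on it. Itih4 (174-fold, 159 to 190.5), Mcam (146-fold, 134 to 159) and Nrarp (86-fold, 71.4 to 104) were among the 10 largest folds. Among the largest folds on the Mural3 side were the bradykinin receptor Bdkrb1 (22.6 against 290.1 CPM, 12.8-fold, 12.3 to 13.4) and the matrix gene Efemp1 (111 against 1147 CPM, 10.3-fold, 10.1 to 10.5). Cpz (9.29-fold, 8.92 to 9.69), Adh7 (9.28-fold, 8.96 to 9.62), Col23a1 (8.41-fold, 8.11 to 8.72) and Tnfaip6 (7.63-fold, 7.24 to 8.05) followed. The reporter genes Pdgfrb (3.43-fold, 3.39 to 3.46) and Cspg4 (10.7-fold, 10.4 to 11) were higher in Mural1 and Mural2. Of the markers, 9 of 11 pericyte and 10 of 11 smooth muscle markers were higher in Mural1 and Mural2, and 7 of 10 fibroblast and 4 of 8 adventitial fibroblast markers in Mural3.

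Complement genes were higher in Mural3 in 7 of 14 cases, led by Cfb (7.7-fold, 7.56 to 7.84), C3 (7.37-fold, 7.32 to 7.41) and C4b (4.5-fold, 4.46 to 4.55). Chemokines and their receptors were higher there in 4 of 24, with Ackr3 (2.73-fold, 2.68 to 2.79), Il1r1 (2.32-fold, 2.28 to 2.37) and Cxcl12 (2.04-fold, 2.02 to 2.06). Niche factors gave 5 higher in Mural3, with Sfrp1 (5.64-fold, 5.47 to 5.83) and Fgf10 (5.22-fold, 4.96 to 5.5), and 2 higher in Mural1 and Mural2, of 30. Of 26 calcium genes 5 were higher in Mural1 and Mural2, with Ano1 (11.9-fold, 11 to 13) and Cacna1c (6.62-fold, 6.34 to 6.91). Of 20 potassium channel genes 1, Kcnk3 (39.1-fold, 36.3 to 42.1), was higher and 1, Kcne4 (2.44-fold, 2.39 to 2.48), lower. Vasoactive receptors gave 5 higher, with Tbxa2r (3.84-fold, 3.64 to 4.05) and Ramp1 (3.75-fold, 3.6 to 3.9), and 1, Ptgfr (4.19-fold, 4.07 to 4.31), lower of 41. Basement membrane genes gave 5 higher, with Vtn (79.2-fold, 67.9 to 92.9) and Lama5 (6.63-fold, 6.26 to 7.02), and 1 lower of 21. Fibrillar and elastic genes gave 3, with Postn (24.8-fold, 24.3 to 25.4), and 4, with Ogn (2.77-fold, 2.74 to 2.79), of 27.

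PDGF, VEGF, angiopoietin and Notch genes gave 6 higher in Mural1 and Mural2, with Pdgfa (4.88-fold, 4.69 to 5.08) and Angpt2 (4.29-fold, 4.15 to 4.45), and 2 lower, Angptl4 (3.62-fold, 3.51 to 3.74) and Figf (2.89-fold, 2.81 to 2.96), of 27. TGF-beta and BMP genes gave 3 of 28, with Ltbp2 (12.7-fold, 12.3 to 13.1) and Tgfb2 (2.96-fold, 2.88 to 3.05). Haemostasis genes gave 4 higher, with F3 (2.55-fold, 2.52 to 2.58) and Serpine2 (2.56-fold, 2.52 to 2.59), and 1 lower, Ptgs2 (3.9-fold, 3.78 to 4.02), of 28. Lipid genes gave 2 and 2 of 25, with Lipg (47.5-fold, 42.7 to 52.9) against Apoe (3.54-fold, 3.52 to 3.57) and Lpl (2.99-fold, 2.94 to 3.05). The brain endothelial list gave 2 and 1 of 31, with Tfrc (5.46-fold, 5.16 to 5.78) and Foxf2 (4.42-fold, 4.24 to 4.61) against Slco2b1 (2.79-fold, 2.73 to 2.85). Of 21 pulmonary hypertension risk genes 1 passed, Kcnk3. Transcription factors gave 3 higher, with Epas1 (6.38-fold, 6.26 to 6.5) and Mef2c (2.38-fold, 2.32 to 2.45), and 1 lower, Klf4 (2.28-fold, 2.22 to 2.34), of 38. Stress genes split 3 to 4 of 16, with Hspb1 (6.01-fold, 5.7 to 6.35) and Hspa1a (3.96-fold, 3.87 to 4.05) against Ier2 (2.68-fold, 2.65 to 2.72).

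Antigen presentation genes were higher in Mural1 and Mural2 in 4 of 15 cases, H2-Aa (3.71-fold, 3.65 to 3.76), Cd74 (3.53-fold, 3.5 to 3.56), H2-Eb1 (3.27-fold, 3.22 to 3.33) and H2-Ab1 (3.16-fold, 3.12 to 3.21). They went with epithelial markers, 6 of 11 higher, and the leukocyte marker Lyz2. Without Mural2 all 4 turned, to log2 differences of -1.80, -1.80, -1.75 and -1.84. Without clusters 4 and 8 they were 0.45, 1.07, 1.23 and 1.05, so H2-Aa fell below 2-fold and the other 3 stayed above it. Cd74 stood at 10340 CPM in cluster 4, 1558 CPM in cluster 8 and 67.6 CPM in the other mural-set cells. Col12a1 (2.82-fold, 2.75 to 2.89) turned to -0.30 without Mural1 and Atf3 (3.13-fold, 3.08 to 3.18) to -0.23 without Mural2. Of 81 named genes that passed, 9 moved by over 1.5 times without Mural1, among them Col8a1 (3.61, and 1.47 without it), and 25 without Mural2. Of the 669 genes, 633 had 1 direction in both sets and 440 the fold in each. Scaling turned the balance, since TMM factors shifted the median log2 difference by -0.40 and gave 281 higher and 523 lower. Median-ratio factors, with a shift of -0.41, gave 275 and 550. Of the 669 genes 495 also passed under TMM. At 4-fold 165 genes were higher in Mural1 and Mural2 and 32 in Mural3.

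Within Cldn5-eGFP cells, 74 aerocyte-like cells were set against 680 other endothelial cells, 658 of them general capillary-like. Of the 11103 genes the clusters had not used 119 passed, 60 higher and 59 lower in aerocyte-like cells. The aminopeptidase gene Xpnpep2 (343 against 0.323 CPM, 1061-fold, 789.5 to 1461) had the largest fold, followed by Frrs1 (374 against 4.21 CPM, 88.7-fold, 81.5 to 96.7) and Pcolce2 (87.8-fold, 79.6 to 96.9). Itgb5 (313 against 7.5 CPM, 41.7-fold, 39.1 to 44.6), an integrin subunit, Dpysl5 (61.6-fold, 55.7 to 68.3), Tmeff2 (41.5-fold, 39.5 to 43.5) and Abcc3 (36.3-fold, 34.1 to 38.7) were also higher. The VEGF receptor gene Kdr (3732 against 604 CPM, 6.18-fold, 6.12 to 6.24) and the thromboxane receptor gene Tbxa2r (267 against 24.4 CPM, 10.9-fold, 10.5 to 11.4) were higher in aerocyte-like cells. So were the adhesion gene Icam1 (1845 against 323 CPM, 5.71-fold, 5.63 to 5.78) and the chemokines Cx3cl1 (542 against 82.9 CPM, 6.54-fold, 6.38 to 6.71) and Cxcl16 (6.12-fold, 5.91 to 6.34). Lower in them were the VEGF ligand Vegfa (1.31 against 261 CPM, 199-fold, 140.1 to 293), the chemokine Cxcl12 (1.99 against 853 CPM, 429.5-fold, 323 to 584) and the taurine transporter Slc6a6 (1.01 against 599.8 CPM, 591-fold, 398 to 923). The angiopoietin receptor Tek (227 against 2376 CPM, 10.5-fold, 10.2 to 10.8), Sox17 (95.2-fold, 76.5 to 119.9), Edn1 (57.8-fold, 50.2 to 66.8) and Iigp1 (754-fold, 366 to 1875) were lower as well.

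Antigen presentation was the list with most members on one side: 5 of 15 were lower in aerocyte-like cells and none higher, with H2-DMb1 (at least 794-fold), H2-Ab1 (119-fold, 106 to 136) and Cd74 (62-fold, 57.7 to 66.7). Counts are given aerocyte-like side first. Chemokines split 2 to 2 of 24, and haemostasis genes 3 to 2 of 28, with Icam1 against Edn1 and Entpd1 (12.2-fold, 11.2 to 13.2). The PDGF and VEGF list had 1 higher, Kdr, and 2 lower, Vegfa and Tek, of 27. Vasoactive receptors gave 1 higher, Tbxa2r, and 1 lower, Npr3 (36.6-fold, 31 to 43.5). Basement membrane genes gave 1, Lamc1 (4.6-fold, 4.42 to 4.8), and 1, Lama5 (5.19-fold, 4.89 to 5.5), and pulmonary hypertension risk genes 1, Kdr, and 1, Sox17. Of brain endothelial list genes 2 of 31 were lower, Slc6a6 and Abcb1a (15.7-fold, 13.5 to 18.2), of lipid genes 1, the lipase gene Lpl (41.7-fold, 36.3 to 48.1), and of BMP genes 1, Bmp6 (5.25-fold, 5.04 to 5.47). One-sided single members were Col12a1 (16.9-fold, 16.2 to 17.7) of the fibrillar list, Fgf1 (4.8-fold, 4.67 to 4.94) of the niche list and Hspb1 (9.14-fold, 8.42 to 9.93) of the stress list. Transcription factors gave 1, Meox1 (6.15-fold, 5.86 to 6.45), and 1, Hoxa5 (21.6-fold, 18.4 to 25.6), and no potassium, calcium or complement gene passed. All 119 genes had 1 direction in EC1, EC2 and EC3 and 78 the fold in each. Leaving out EC1, EC2 or EC3 moved 11, 13 and 14 of 42 named genes by over 1.5 times, among them H2-Eb1 (-5.49, and -10.57 without EC3). TMM factors shifted the median log2 difference by 0.31 and gave 77 higher and 48 lower.

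The 658 general capillary-like cells against the 96 aerocyte- and lymphatic-like cells gave 106 genes, 51 higher and 55 lower, largely the same cells as in the aerocyte comparison seen from the other side. Higher in general capillary-like cells were Slc6a6 (462-fold, 339.5 to 647), Vegfa (244-fold, 173 to 354) and H2-Ab1 (151-fold, 134 to 172). Cd74 (80.3-fold, 74.8 to 86.4), Lpl (54-fold, 47.1 to 62.3) and the multidrug transporter Abcb1a (20.4-fold, 17.6 to 23.7) were also higher. Lower were Xpnpep2 (1121-fold, 793 to 1640), Nrp2 (26.8-fold, 25.1 to 28.6) and Abca1 (9.21-fold, 8.82 to 9.62). Antigen presentation had 5 of 15 higher, and all 106 genes had 1 direction in the 3 sets. Leaving out EC1, EC2 or EC3 moved 12, 10 and 14 of 43 named genes by over 1.5 times, among them Edn1 (6.22, and 11.28 without EC3), and TMM shifted the median log2 difference by -0.16.

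The 22 lymphatic-like cells against 732 other endothelial cells gave 340 genes, 175 higher and 165 lower. The pentraxin Ptx3 (769.9 against 0.0909 CPM, 8469-fold, 5042 to 15503), the transcription factor Tbx1 (358 against 0.0909 CPM, 3934-fold, 2340 to 7209) and Klhl4 (2649-fold, 1710 to 4346) were among the largest folds. Ceruloplasmin, Cp (1682 against 2.36 CPM, 712-fold, 641 to 792), the mannose receptor Mrc1 (938 against 2.34 CPM, 400.1-fold, 359.6 to 446) and the placental growth factor gene Pgf (343-fold, 279.8 to 425) were also higher. Lower in lymphatic-like cells were Cd74 (0.684 against 1756 CPM, 2567-fold, 1003 to 9423), Ly6c1 (1658-fold, 841 to 3840) and Ly6a (1851-fold, 1211 to 2991). The prostaglandin-degrading enzyme gene Hpgd (1818-fold, 1016 to 3643) and the VEGF co-receptor Nrp1 (1609-fold, 781 to 4001) were lower too. 

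Of 28 TGF-beta and BMP genes 8 were lower in lymphatic-like cells, with Bmp6 (1364-fold, 378 to 11262, 2 reads on the lower side) and Smad7 (at least 523-fold), and 2 higher, with Tgfb3 (191-fold, 170.0 to 215). Of 21 pulmonary hypertension risk genes 5 were lower, including Bmpr2 (21.3-fold, 19.8 to 23) and Acvrl1 (23.6-fold, 21.9 to 25.5), and 1 higher, Smad1 (8.17-fold, 7.83 to 8.52). Counts below give the lymphatic-like side first. PDGF, VEGF and Notch genes split 4 to 6 of 27, with Flt1 (1008-fold, 345 to 4889, 3 reads on the lower side) and Notch4 (343-fold, 158 to 936) lower, and antigen presentation 0 to 5 of 15. Vasoactive receptors split 0 to 3 of 41, with Adrb1 (at least 550.4-fold) and Calcrl (6.6-fold, 6.37 to 6.84) lower. Transcription factors split 1 to 5 of 38, with Epas1 (52.6-fold, 48.5 to 57.1) and Tbx3 (672-fold, 229.8 to 3257, 3 reads on the lower side) lower. Potassium channel genes were higher in 2 of 20, Kcnj8 (53.6-fold, 49.5 to 58.1) and Kcnn3 (45.5-fold, 42.5 to 48.9). Basement membrane genes split 4 to 1 of 21, with Nid2 (152-fold, 139 to 167) and Lama4 (28.9-fold, 28 to 29.8) higher, and fibrillar and elastic genes 4 to 1 of 27, with Ltbp4 (38.8-fold, 37.9 to 39.7) higher. Haemostasis genes split 3 to 5 of 28, and lipid genes 1 to 4 of 25, with Abca1 (30.3-fold, 29.1 to 31.5) against Lpl (1848-fold, 332 to 72988, 1 read on the lower side). Brain endothelial list genes split 2 to 2 of 31, chemokines 1 to 2 of 24 and calcium genes 1 to 2 of 26, with Piezo2 (28.4-fold, 22.1 to 37.4) lower. Of niche factors 2 were higher, with Rspo3 (176-fold, 153 to 203), of stress genes 1, Egr1 (62.5-fold, 59.2 to 66.1), and no complement gene passed. The sets held 7, 6 and 9 lymphatic-like cells, 314 of the 340 genes had 1 direction in the 3 and 213 the fold in each, and in simulated data with these cell numbers 84 of 10983 unaltered genes passed among the genes compared. TMM factors shifted the median log2 difference by -0.22 and gave 150 higher and 182 lower.

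Pericyte-like cells (68) and smooth muscle-like cells (70) of Mural1 and Mural2 differed in 480 of 11103 genes past the 4-fold rule, 234 higher in pericyte-like and 246 in smooth muscle-like cells. Pericyte-like cells had more of Vtn (715 against 0.45 CPM, 1587-fold, 835 to 3471), which encodes vitronectin, and the basement membrane gene Nid2 (272 against 0.30 CPM, 905-fold, 416 to 2469). The adenylate cyclase Adcy8 (669.8-fold, 457 to 1026), the endothelial lipase gene Lipg (941 against 2.8 CPM, 336-fold, 258 to 445) and the erythropoietin receptor Epor (at least 480.4-fold) were also higher in them. Tmem200a (4708-fold, 1303 to 38881, 2 reads on the lower side), Cdk18 (1797-fold, 614 to 8720, 3 reads on the lower side) and Plxdc1 (569.8-fold, 339 to 1043) were among the 10 largest folds. Smooth muscle-like cells had more of Itih4 (0.338 against 2877 CPM, 8517-fold, 3326 to 31259) and the ATP-gated channel P2rx1 (0 against 795 CPM, at least 3136-fold). Tissue factor, F3 (0.845 against 1063 CPM, 1258-fold, 684 to 2624), and Ramp1 (0.253 against 308 CPM, 1215-fold, 416 to 5894, 3 reads on the lower side), a partner of the calcitonin-receptor-like receptor, were also higher in them. The neurotrophin Ntf3 (2896-fold, 519.6 to 114427, 1 read on the lower side) and the neurotrophin receptor Ntrk3 (at least 973-fold) were both on this side, with Plin4 (at least 806-fold) and Hspb7 (3452-fold, 619 to 136381, 1 read on the lower side). Pdgfrb was higher in pericyte-like cells, at 6169 CPM (6124 to 6214) against 703 CPM (692 to 715). Cspg4, at 1348 CPM (1327 to 1369) against 818 CPM (805 to 830.4), did not pass.

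Splits are given pericyte-like side first. Of 41 vasoactive receptors 3 were higher in pericyte-like cells, including the angiotensin receptor Agtr1a (91.2-fold, 76.5 to 109.7), and 3 in smooth muscle-like cells, including P2rx1 and Ramp1. Of 20 potassium channel genes 3 were higher in smooth muscle-like cells, the voltage-gated Kcna5 (2089-fold, 375 to 82549, 1 read on the lower side) and Kcna2 (at least 382-fold) and the calcium-activated channel subunit Kcnmb1 (6.11-fold, 5.66 to 6.6), and 1 in pericyte-like cells, Kcnq5 (122-fold, 91.6 to 168). Calcium genes were higher in pericyte-like cells in 3 of 26, with Itpr2 (11.5-fold, 10.7 to 12.4). Fibrillar and elastic genes split 4 to 5 of 27, with Eln (43.3-fold, 39.9 to 47.1), Loxl1 (20.6-fold, 18.8 to 22.8) and Lox (20.4-fold, 15.4 to 27.4) on the smooth muscle side. Basement membrane genes split 7 to 4 of 21, with Lama5 (68-fold, 50.2 to 94.5) and Col4a6 (48.8-fold, 35.3 to 69.5) on the smooth muscle side. TGF-beta and BMP genes split 4 to 4 of 28, with Ltbp2 (113-fold, 103 to 125) and Bmp4 (48.2-fold, 39.6 to 59.3) against Id2 (21.2-fold, 19.4 to 23.4) and Tgfb3 (16.3-fold, 14.4 to 18.4). PDGF and Notch genes split 4 to 1 of 27, with Nrp2 (150.4-fold, 93.6 to 259), Notch1 (7.63-fold, 7.12 to 8.18) and Pdgfa (7.26-fold, 6.87 to 7.69) in pericyte-like cells.

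Chemokines and cytokines gave 4 higher in pericyte-like cells, with Tslp (259-fold, 144 to 519), Il34 (245-fold, 139.6 to 474) and Cxcl14 (109-fold, 83.3 to 145), and 2 lower of 24. Niche factors split 5 to 5 of 30, with Wnt4 (44.4-fold, 36.7 to 54.3) and Wnt5a (86.3-fold, 56.7 to 138) against Wisp2 (60.8-fold, 49 to 76.2). Transcription factors split 5 to 2 of 38, with Nr2f1 (67.1-fold, 49.6 to 93.1) against Gata6 (490.2-fold, 168 to 2379, 3 reads on the lower side). Haemostasis genes split 4 to 5 of 28, with Plat (55.8-fold, 48.5 to 64.5) against Ptgis (31.9-fold, 26.8 to 38.3). Pulmonary hypertension risk genes split 2 to 2 of 21, with Tbx4 (8.56-fold, 8.07 to 9.08) against Cav1 (10.8-fold, 10.3 to 11.4), and lipid genes 2 to 2 of 25. Brain endothelial list genes were higher in pericyte-like cells in 2 of 31, Lef1 (287-fold, 176 to 502) and Foxf2 (32.4-fold, 29.1 to 36), both transcription factors. Complement gave 2 of 14 on the smooth muscle side, with C4b (37.4-fold, 32.3 to 43.5), and no antigen presentation gene passed. Stress genes were higher in smooth muscle-like cells in 11 of 16, with Atf3 (147-fold, 127 to 171) and Nr4a1 (82.6-fold, 73.7 to 92.8). So were epithelial markers (581.5 against 3820 CPM). In Mural2 class was not separated from plate row. Of the 480 genes 479 had 1 direction in Mural1 and in Mural2 and 385 the fold in each. Leaving out Mural1 moved 31 of 71 named genes by over 1.5 times, among them Loxl1 (-4.37, and -8.46 without it). TMM factors shifted the median log2 difference by -0.26 and gave 196 and 298.

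Against 85 fibroblast-like cells of the same sets, the 68 pericyte-like cells differed in 499 genes, 247 higher and 252 lower. Pericyte-like cells had more of the lipase gene Lipg (941 against 0.067 CPM, 14047-fold, 3888 to 116005, 2 reads on the lower side) and the Notch target Nrarp (450.4 against 0.168 CPM, 2688-fold, 1151 to 8282). The growth factor Hbegf (637 against 0.302 CPM, 2112-fold, 1112 to 4620), the G-protein regulator Rgs4 (491 against 1.24 CPM, 396-fold, 287 to 563) and Vsnl1 (661-fold, 386 to 1243) were also higher in them. Fibroblast-like cells had more of the matrix protease Mmp3 (0.422 against 2271 CPM, 5378-fold, 2305 to 16565) and the BMP family member Gdf10 (0.338 against 1070 CPM, 3167-fold, 1237 to 11626). Podn (2266-fold, 885 to 8319), Cpxm1 (at least 2100-fold), F3 (1558-fold, 847 to 3249) and the opioid precursor gene Penk (974-fold, 333 to 4725, 3 reads on the lower side) followed. The reporter genes Pdgfrb (7.81-fold, 7.7 to 7.93) and Cspg4 (15-fold, 14.4 to 15.7) were higher in pericyte-like cells.

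Complement was on the fibroblast side in 10 of 14 genes, with C3 (708-fold, 537 to 954), C7 (373-fold, 291 to 487) and Cfb (273-fold, 163 to 500.1). Fibrillar and elastic genes were there in 9 of 27, with Fbln2 (405-fold, 269.6 to 638), while Postn (71.7-fold, 69.5 to 73.9) was the 1 higher in pericyte-like cells. With the pericyte-like side first, niche factors split 2 to 7 of 30, with Wnt4 (91.6-fold, 73.2 to 116) against Igf1 (434-fold, 263 to 776). Chemokines split 3 to 5 of 24, with Cxcr4 (104-fold, 73.7 to 152) against Cxcl12 (79.2-fold, 69.1 to 91.3) and Ackr3 (106-fold, 76.5 to 152). Calcium genes were higher in pericyte-like cells in 6 of 26, with Trpv2 (173-fold, 104 to 309.5). Potassium channel genes were higher in 2 of 20, with Kcnk3 (70.0-fold, 63.7 to 77.1), and lower in 1, Kcnt2 (224-fold, 76.5 to 1087, 3 reads on the lower side). Vasoactive receptors split 4 to 1 of 41, with Agtr1a (85.9-fold, 74.6 to 99.3), S1pr3 (15-fold, 14.5 to 15.6) and Ednra (6.96-fold, 6.74 to 7.2) against Ptgfr (188-fold, 98.7 to 410.4). Basement membrane genes split 4 to 4 of 21, with Vtn (83.7-fold, 73.8 to 95.1) against Col4a3 (29.1-fold, 21.5 to 40.2) and Col4a4 (78.5-fold, 49.6 to 133).

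PDGF and Notch genes split 6 to 2 of 27, with Notch1 (27.2-fold, 24.6 to 30.1) and Pdgfa (23-fold, 21.2 to 24.8) against Figf (23.6-fold, 19.2 to 29.4) and Tek (9.46-fold, 8.0 to 11.3). TGF-beta and BMP genes split 2 to 3 of 28, with Ltbp2 (10.2-fold, 9.97 to 10.5) against Tgfb3 (17.2-fold, 15.3 to 19.5), and pulmonary hypertension risk genes 3 to 1 of 21, with Tbx4 (9.22-fold, 8.76 to 9.71) against Cav1 (4.55-fold, 4.33 to 4.78). Haemostasis genes split 2 to 4 of 28, with Ace (115-fold, 84.5 to 159.9) and Ptgis (42-fold, 35.3 to 50.3) on the fibroblast side. Brain endothelial list genes split 2 to 1 of 31, with Slco2b1 (251-fold, 147 to 472) on that side, and lipid genes 3 to 4 of 25, with Abca8a (149.9-fold, 123 to 185) there. Transcription factors split 5 to 5 of 38, with Epas1 (15.4-fold, 14.8 to 16) and Nr2f1 (127-fold, 90.4 to 184) against Osr1 (911-fold, 311 to 4417, 3 reads on the lower side). Stress genes were higher in fibroblast-like cells in 9 of 16, with Nr4a1 (26.8-fold, 23.9 to 30.2) and Egr1 (13.6-fold, 12.9 to 14.3). All 499 genes had 1 direction in both sets and 395 the fold in each. Of 81 named genes 38 moved by over 1.5 times without Mural1, among them Vtn (6.39, and 11.80 without it), and 51 without Mural2, among them Lef1 (5.08, and 9.36). TMM factors shifted the median log2 difference by -0.46 and gave 176 higher and 324 lower.

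The 4 fibroblast-like clusters of Mural3 were each set against the other fibroblast-like cells of that set, at 4-fold. In cluster 2 (77 cells) 13 genes were higher and 22 lower. The basement membrane collagens Col4a4 (89.4 against 3.28 CPM, 27.2-fold, 24.1 to 30.9) and Col4a3 (118 against 5.01 CPM, 23.6-fold, 21.4 to 26.1) were higher. So were Ackr3 (5.4-fold, 5.29 to 5.51), a receptor that takes up Cxcl12, the complement regulator Cd55 (5.56-fold, 5.37 to 5.76) and Thbs2 (4.54-fold, 4.39 to 4.69). Bmp5 (2.96 against 164 CPM, 55.3-fold, 44.6 to 69.5), Tbx4 (10.2-fold, 8.93 to 11.7), Il6 (7.79-fold, 7.0 to 8.68) and Aqp1 (5.89-fold, 5.68 to 6.1) were lower.
Cluster 3 (127 cells) had 2 genes higher, the chemokine Ccl8 (109.9 against 12.9 CPM, 8.52-fold, 7.93 to 9.16) and Aox3 (4.12-fold, 3.95 to 4.29). Of its 17 lower genes, the integrin Itga8 (0.803 against 122 CPM, 151-fold, 110.1 to 214), Aqp1 (20.2-fold, 19.3 to 21.1), Thbs1 (12.9-fold, 12.4 to 13.3) and F2r (7.99-fold, 7.64 to 8.35) were among the named.
Cluster 5 (86 cells) had 26 genes higher, including the WNT inhibitor Notum (92.8 against 2.15 CPM, 43.1-fold, 37 to 50.4), Aqp1 (27.6-fold, 26.9 to 28.4), Bmp7 (22.9-fold, 20.8 to 25.3) and the T-type calcium channel Cacna1g (7.32-fold, 6.71 to 7.99). Its 24 lower genes included the retinoic acid enzyme gene Aldh1a3 (0.187 against 127 CPM, 681-fold, 313 to 1855), Ebf2 (126-fold, 79.5 to 212), Sfrp4 (18.3-fold, 16.8 to 19.9) and Fn1 (6.92-fold, 6.73 to 7.12).
Cluster 10 (23 cells) had 91 higher and 72 lower. The cytokine Il34 (97.8 against 1.12 CPM, 87.6-fold, 72.2 to 107), the potassium channel Kcnk3 (164-fold, 121 to 229), the lysophosphatidic acid enzyme gene Enpp2 (37.2-fold, 36.2 to 38.2) and Ltbp2 (21.9-fold, 20.6 to 23.3) were higher. The alarmin Il33 (1.04 against 328 CPM, 316-fold, 161 to 733), Cfb (10.7-fold, 10.0 to 11.5) and Ackr3 (23.7-fold, 19.9 to 28.4) were lower. TMM factors shifted the median log2 difference by 0.17 for cluster 3, giving 2 and 13, and by -0.20 for cluster 10, giving 77 and 93. In simulated data with the cell numbers of cluster 10, 12 of 10990 unaltered genes passed among the genes compared. At resolution 0.5 cluster 3 gave 6 higher and 18 lower and cluster 5 35 and 39, and at resolution 2 they gave 1 and 15, and 43 and 47.

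Cluster 2, the only fibroblast-like cluster with 20 or more cells on both sides, was compared between Mural1 and Mural2 (64 cells) and Mural3 (77 cells). At 2-fold 186 genes were higher in Mural1 and Mural2 and 192 in Mural3. The matrix genes Eln (1447 against 379 CPM, 3.81-fold, 3.73 to 3.9) and Fmod (171 against 31.1 CPM, 5.5-fold, 5.11 to 5.93) were higher in Mural1 and Mural2, with F3 (5.21-fold, 5.09 to 5.34), Dkk3 (3.43-fold, 3.33 to 3.52) and the chemokine Ccl8 (5.25-fold, 4.79 to 5.78). Higher in Mural3 were Thbs2 (14 against 325 CPM, 23.2-fold, 20.7 to 26), the WNT inhibitor Sfrp1 (48.1 against 440.3 CPM, 9.16-fold, 8.6 to 9.76) and Igfbp5 (10.3-fold, 9.86 to 10.7), which encodes a growth factor binding protein. The complement genes C3 (2458 against 8487 CPM, 3.45-fold, 3.42 to 3.48) and C4b (2.46-fold, 2.4 to 2.52) were also higher there. Complement gave 3 of 14 higher in Mural3 and 0 lower, chemokines 2 and 1 of 24, and fibrillar and elastic genes 4 and 2 of 27. Pdgfrb (2.26-fold, 2.2 to 2.31) was higher in Mural1 and Mural2. Apod (10.2-fold, 9.97 to 10.4) ranged from 0.594- to 21.9-fold over the sets and turned to a log2 difference of -0.75 without Mural1. With clusters made from the other random part of the genes Ptgs2 (3.73-fold, 3.55 to 3.93) turned to 0.33 and C4b to 0.12. Of the 378 genes 369 had 1 direction in both sets and 176 the fold in each. In simulated data with these cell numbers 148 of 21747 unaltered genes passed. Without Mural2, with 31 cells left on that side, the count was 773, and without Mural1, with 33 left, 516. Without Mural1 16 of 48 named genes moved by over 1.5 times, among them Pcsk6 (-2.60, and -7.31 without it), and without Mural2 19.

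Placed over classes, 383 of 432 measured list entries reached 10 CPM in some class, chondrocyte- or perichondrial-like cells included. Of these 84 were highest by at least 2-fold in the endothelial class, 86 in mural, 90 in fibroblast and 123 in none. The lead was taken among these pooled classes, without chondrocyte- or perichondrial-like cells. Antigen presentation was endothelial in 14 of 15, led by H2-DMb1, at 105 CPM (104 to 107) in general capillary-like cells. Complement was fibroblast in 10 of 12, led by C3, at 12031 CPM (12000 to 12063) in cluster 3 of Mural3. Fibrillar and elastic matrix was fibroblast in 16 of 27, and mural in 2, with Postn at 10204 CPM (10147 to 10262) in pericyte-like cells. Niche factors were fibroblast in 14 of 27 and endothelial in 0, with Igf1 at 765 CPM (745 to 784) in cluster 10 of Mural3. Vasoactive receptors were mural in 16 of 35, endothelial in 8 and fibroblast in 7, with Adra1d at 142 CPM (137 to 147) in smooth muscle-like cells and S1pr1 at 1877 CPM (1860 to 1895) in aerocyte-like cells. Calcium genes were mural in 11 of 25 and potassium channel genes in 7 of 17, with Kcna5 at 176 CPM (171 to 182) in smooth muscle-like cells.

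PDGF, VEGF, angiopoietin and Notch genes were endothelial in 10 of 27 and mural in 6, and pulmonary hypertension risk genes in 7 and 3 of 17. TGF-beta and BMP genes were endothelial in 7 of 24 and mural in 4, with Bmp6 at 533 CPM (529 to 537) in general capillary-like and Ltbp2 at 2258 CPM (2231 to 2285) in pericyte-like cells. Haemostasis genes were endothelial in 10 of 24, with Edn1 at 502 CPM (498 to 506) in general capillary-like cells. Brain endothelial list genes were endothelial in 7 and mural in 7 of 22, with the tight junction gene Ocln at 182 CPM (176 to 187) in aerocyte-like and the transcription factor gene Lef1 at 229.5 CPM (221 to 238) in pericyte-like cells, which was 149.2 CPM (138.7 to 160.3) without Mural2. Lipid genes were endothelial in 4, mural in 5 and fibroblast in 5 of 21, with Cd36 at 7337 CPM (7303 to 7372) in aerocyte-like and Abca8a at 1416 CPM (1400 to 1431) in cluster 2 of Mural1 and Mural2. Transcription factors were endothelial in 8, mural in 5 and fibroblast in 8 of 32. Chemokines were 2, 4 and 6 of 21 in the same order, basement membrane genes 0, 4 and 6 of 21, and stress genes 0, 4 and 3 of 16. Fmod, placed as fibroblast, stood at 9899 CPM (9823 to 9976) in the chondrocyte- or perichondrial-like cluster 13, and at 5451 CPM (5296 to 5609) without Mural1, with 3 cells left. With fibroblast-like cells of Mural1 and Mural2 alone, 30 of 424 genes were placed differently, of which 1, Thbs2, went to another class.

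**Figure D3:**
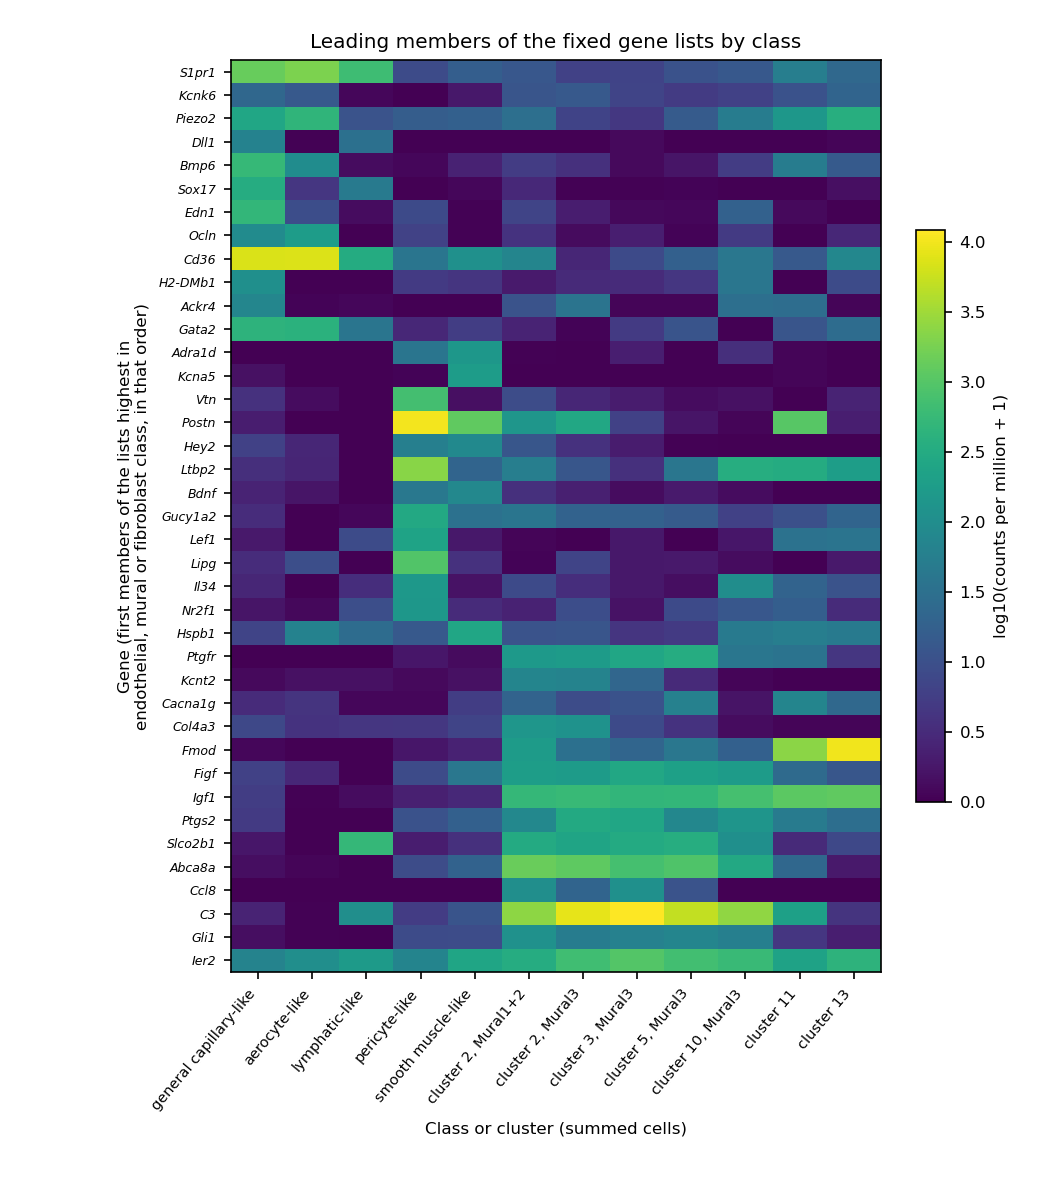
Colour gives the level, log10 of CPM plus 1, of 39 list genes (y axis, members first placed for the lists in the endothelial, mural or fibroblast class) in the summed cells of 12 classes or clusters (x axis). H2-DMb1 is highest in general capillary-like cells (105 CPM) and Postn in pericyte-like cells (10204 CPM), and C3 peaks in cluster 3 of Mural3 (12031 CPM).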

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

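Of the tests in this part, the one on sequencing depth was chosen only after the result was seen.

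Reads of the reporter transgene eGFP, which no comparison between cells used, were above the limit that a count of 0 allows in all classes looked at. They stood at 3414 CPM (3405 to 3423) in Cldn5-eGFP cells, 3311 CPM (3278 to 3344) in pericyte-like cells, 484 CPM in smooth muscle-like cells and 306 CPM in fibroblast-like cells, over all mural sets. Within Mural1 and Mural2 the order of the last 2 turned, with 483 CPM (473 to 493) in smooth muscle-like and 505 CPM (497 to 513) in fibroblast-like cells, and Mural3 fibroblast-like cells had 255 CPM (252 to 258).

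Clusters 4 and 8, which no class comparison used, carried transcripts of epithelial cells and leukocytes far above the level in the other cells of the mural sets. In cluster 4, Sftpc, a surfactant gene of alveolar epithelium, stood at 94490 CPM and the lysozyme gene Lyz2 of macrophages and neutrophils at 25685 CPM, against 421 and 89 CPM in the other mural-set cells. In cluster 8, Scgb1a1, a secretory gene of airway epithelium, stood at 47352 CPM, against 159.8 CPM. All epithelial and leukocyte markers summed to 163064 CPM in cluster 4 and 76529 CPM in cluster 8.

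Levels in CPM and shares after thinning do not rise with depth by construction, so the test on deeper sequencing had no bearing on the pattern. In it, clusters 4 and 8 in the mural sets had a median of 246104 reads, against 338919 in other mural-set cells. Sets of differing depth were pooled. Free RNA or debris spread over the rows of these wells remains open for part of the pattern. Named-class cells had 5764 marker CPM in rows G to L of Mural2 (22 cells), 2.47 times the 2330 of other rows. In rows A to D of Mural3 they had 1692, 10.3 times the 164 of other rows. All lay far below clusters 4 and 8. A sorted mural or fibroblast cell with other cells in 1 well also remains open. At least 3 fibroblast, pericyte or smooth muscle markers had reads in 98.97% of cluster 4, 90.0% of cluster 8 and 11.5% of endothelial-class cells. Debris in mural-sorted wells would leave such reads too, so they cannot decide. The mural sort should have removed epithelial cells and leukocytes that came alone. No biological explanation was tested.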

How the results depend on the processing

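The alternatives that left out clusters 4 and 8 or a column set, the TMM factors for class comparisons and the restriction to fibroblast-like cells of Mural1 and Mural2 were chosen after seeing the data. Of 314 alternative values of the counts and shares that answer a comparison, 284 stayed within 1.5 times the count or within the interval of the share, 30 moved and 0 reversed, since a total or a share has no direction. Which side held more genes did turn in some alternatives, given below. Of 10620 alternative values of named genes 5955 stayed within the counting interval, 4656 moved and 9 reversed. Keeping cells under 50000 reads gave no separate values, since no cell had fewer. A column set was not left out where under 20 cells would remain on a side, as for lymphatic-like cells and, for Mural2, pericyte- against smooth muscle-like cells. No paired analysis was possible because no replicate number is carried by the columns and no test was run. Resolutions of 0.5 and 2 gave the same endothelial, pericyte- and smooth muscle-like cells as resolution 1, so they are no separate check of those comparisons. Depth limits folds whose lower side holds 3 reads or fewer and comparisons of few cells, such as those of 22 lymphatic-like cells.

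Without a minimum CPM or share of cells, which by construction lets in genes with few reads, the counts grew. They were 6407 for Cldn5-eGFP against Mural3, 5628 for Cldn5-eGFP against Mural1 and Mural2, and 8155 for Mural1 and Mural2 against Mural3. For classes they were 3217 (general capillary), 3432 (aerocyte), 3785 (lymphatic), 2821 (pericyte against smooth muscle) and 2969 (pericyte against fibroblast). For clusters 2, 3, 5 and 10 of Mural3 they were 1697, 1751, 1726 and 2547, and for cluster 2 between populations 6666. Which side held more genes turned in Cldn5-eGFP against Mural3 (448 higher and 566 lower, then 3936 and 2471), general capillary (51 and 55, then 2492 and 725), aerocyte (60 and 59, then 598 and 2834) and lymphatic (175 and 165, then 1569 and 2216). It also turned in pericyte against smooth muscle (234 and 246, then 1575 and 1246), pericyte against fibroblast (247 and 252, then 1888 and 1081), cluster 5 (26 and 24, then 795 and 931) and cluster 2 between populations (186 and 192, then 3411 and 3255). At 4-fold, a stricter rule by construction, 197 genes separated Mural1 and Mural2 from Mural3.

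For the remaining values the cause was not tested. Cluster 2 differed between populations in 773 genes without Mural2, with 31 cells left, and in 516 without Mural1, with 33. The side with more genes turned under TMM factors in Mural1 and Mural2 against Mural3 (455 and 214, then 281 and 523, and 275 and 550 under median-ratio factors), lymphatic (then 150 and 182), cluster 10 (91 and 72, then 77 and 93), cluster 5 (then 25 and 26) and cluster 2 between populations (then 208 and 175). Small turns came without EC2 in aerocyte (60 and 61), without Mural2 in pericyte against fibroblast (302 and 286) and cluster 2 between populations (401 and 372), and in the latter with means over cells or the authors' scores (198 and 197). Cluster 5 turned at resolution 0.5 (35 and 39) and differed in 90 genes at resolution 2 (43 and 47). Cluster 3 had 6 higher genes at resolution 0.5, against 2. With the other random part of the genes 19 list genes passed in cluster 2 between populations, against 32. By marker score 68.7% of Cldn5-eGFP cells were general capillary-like. With doublet-like cells left out, clusters 4 and 8 held 16.4% of Mural1 and Mural2. With 1000 variable genes cluster 3 held 4.16% of Mural1 and Mural2. In Mural3 the share of cluster 2 was 28.9% with all genes, 8.56% with the other random part and 12.3% with thinned cells. That of cluster 3 was 41.4% at resolution 0.5, 48.1% with 1000 variable genes and 42.5% with thinned cells. That of cluster 5 was 15.5% at resolution 0.5, 11.2% at resolution 2, 14.7% with all genes and 10.4% with 1000 variable genes.

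Reversals of named genes were few, and their cause was not tested. In Mural1 and Mural2 against Mural3, Col12a1 had a log2 difference of -0.30 without Mural1. Without Mural2 the differences were -1.80 for H2-Aa, -1.80 for Cd74, -1.75 for H2-Eb1, -1.84 for H2-Ab1 and -0.23 for Atf3. In cluster 2 between populations, Apod had -0.75 without Mural1, and with the other random part of the genes Ptgs2 had 0.33 and C4b 0.12.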

Other observations

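Of the tests in this part, those of a common plate layout and of matched cell numbers were chosen only after the results were seen.

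Some ligand and receptor genes, picked after the results were seen, had the following levels by class. The endothelin gene Edn1 stood at 502 CPM (498 to 506) in general capillary-like cells and 8.32 CPM (7.2 to 9.57) in aerocyte-like cells, the latter 0.170 CPM (0.0206 to 0.616) without EC3. Its receptor gene Ednra stood at 1087 CPM (1068 to 1106) in pericyte-like cells, 299 CPM (291 to 306) in smooth muscle-like cells and 0.0153 CPM (0.00186 to 0.0554) in general capillary-like cells. Vegfa stood at 272 CPM (269 to 275) in general capillary-like cells and 1.31 CPM (0.89 to 1.86) in aerocyte-like cells (0.170 CPM without EC3), and its receptor gene Kdr at 589 CPM (585 to 593) and 3732 CPM (3707 to 3757). Pdgfb stood at 544 CPM (540.2 to 548) in general capillary-like and 545 CPM (536 to 555) in aerocyte-like cells. Agtr1a, an angiotensin receptor gene, stood at 575 CPM (562 to 589) in pericyte-like and 6.31 CPM (5.25 to 7.51) in smooth muscle-like cells, the latter 0.953 CPM (0.31 to 2.23) without Mural2, with 16 cells left.

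Genes of heritable pulmonary hypertension were spread over endothelial and mural classes. Bmpr2 stood at 2787 CPM (2778 to 2796) in general capillary-like, 2027 CPM (2008 to 2045) in aerocyte-like and 125 CPM (116 to 135) in lymphatic-like cells. Sox17 stood at 338 CPM (335 to 341) in general capillary-like and 3.42 CPM (2.72 to 4.25) in aerocyte-like cells, the latter 1.94 CPM (1.34 to 2.73) without EC2. Kcnk3 stood at 1058 CPM (1039 to 1076) in pericyte-like and 285 CPM (278 to 292) in smooth muscle-like cells, and Tbx4 at 577 CPM (564 to 591) in pericyte-like cells, 138 CPM (134 to 143) in cluster 5 and 8.12 CPM (7.1 to 9.25) in cluster 2 of Mural3.

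In Mural2, pericyte-like and smooth muscle-like cells lay in different plate rows. Rows A to F held 75.6% (59.7 to 87.6) of the pericyte-like cells and 28.8% of all cells, and rows M to P held 59.3% (45.0 to 72.4) of the smooth muscle-like cells and 31.3% of all. A layout common to the plates is argued against in rows M to P only, by a criterion rewritten after a first result. There 80.0% (8 of 10) of these cells in Mural1 and 17.95% (7 of 39) in Mural2 were pericyte-like. Rows A to F (54.55% and 70.45%) leave it open. Transcripts carried over between wells could not be judged, as in pericyte-like cells of rows G to P the summed level of the 10 smooth muscle-side genes of largest fold was 0.662 times (0.123 to 2.34) that in rows A to F, on 3 and 15 reads. No biological explanation was tested.

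Cluster 2 differed between Mural1 and Mural2 and Mural3 in 378 genes. A shift of its make-up towards the other fibroblast-like cells of Mural3 is argued against as the whole cause and stays open for part of the genes. Of 285 genes chosen as higher on 1 random part of its Mural3 cells, 42.5% were higher in those other cells than in the rest. A difference between plates of any kind cannot be told apart from one between populations. Between Mural1 and Mural2 863 genes of this cluster passed, and simulated data gave 524 unaltered genes there and 148 in the comparison of populations, and at matched cell numbers Mural1 differed from Mural3 in 977.5 genes (882 to 1053, median and range over 100 draws). The reporter by which cells were sorted is a biological difference that stays open and was not tested.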
